A study of Mus musculus with 6 samples.

How the data were processed

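The series measured transcripts by RNA sequencing in the duodenum of 6 adult mice, 3 control and 3 mutant, all 6 weeks old and on a mixed strain background. Per the labels' protocols, the first 2 cm of intestine after the stomach were dissected and kept in RNAlater, total RNA was isolated with RNeasy Midi kits, and libraries were made from RNA with an integrity number above 8 using the TruSeq RNA kit. The tissue is the whole wall, so each library mixes epithelium, immune cells, stroma, nerve and muscle. The labels give each mouse its own genotype line and number but no litter, sex, sequencing lane or date. Groups came from the genotype labels.

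Per the submitters' processing notes, CASAVA 1.8.2, TopHat, Cufflinks and DESeq were used with the mouse build mm9. The versions of the last 3 tools, the read counter and the read length are not given in the sources used here. Per the file headers, the authors' per-library tables hold FPKM (fragments scaled by transcript length and by library size) with a confidence interval, 1 table for genes and 1 for RefSeq transcripts. The transcript tables also hold coverage, the mean read depth over a transcript, as the authors deposited it. A further deposited table holds the authors' DESeq comparison, with group means of read counts divided by size factors (a signal that is no longer a whole count), their fold as a ratio and as a log2 value, and unadjusted and adjusted p-values. Gene positions are given 1-based on mm9, and the position of Nkx2-2 was also looked up in the annotation of that build.

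Each gene table has 23699 rows for 23235 symbols, because 248 symbols have several loci. All per-sample columns of FPKM were used. An FPKM value carries no count, so depth was read from the confidence intervals, whose upper bound lies 2 standard errors above the value. Under a Poisson interval this gives the number of reads behind a gene, and for genes with 1 transcript and under 500 such reads 87.8% to 88.2% of values fell within 0.05 of a whole number in each library. The sums of these implied reads were 14.21, 21.25 and 19.91 M (megareads) for control 1, 2 and 3 and 16.88, 25.91 and 21.97 M for mutant 1, 2 and 3. Across single-transcript genes the authors' mean count divided by the mean of implied reads had a median of 1 with quartiles of 0.98 and 1.02. Genes with a low authors' mean were left out of this ratio, which removes some genes where the authors' count is the smaller. The implied reads served as a measure of depth and in 1 added alternative, not in the main test.

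The main test, fixed before the data were examined, was limma 3.58.1 in R 4.3.3 with a trended prior variance on log2(FPKM + 0.1), for rows with a mean FPKM of at least 0.1 over the 6 libraries, with no rescaling, no covariate and no block. Of the rows, 15864 were tested and 7835 were below the filter. All 31 rows marked as failed estimates in any library stayed in. Fold changes are on the log2(FPKM + 0.1) scale, mutant minus control, which understates the change of genes near the pseudocount. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The test was tried on simulated data with the real genes' control means, their moderated variances and independent noise, with 15864 rows and 100 genes changed at each size. It called 69% of genes changed 2-fold and 87.6% of genes changed 4-fold in the comparison of mutant with control, averaged over 5 simulations, with 7.8 false calls on average. The simulation had no effects shared by genes within a library, and its many changed genes ease the adjustment. These shares are therefore not the power in the real data.

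The 33 gene lists, with 369 entries, were also fixed before the data were examined. They are the lists of enteroendocrine hormones, enterochromaffin cells, enteroendocrine transcription factors, secretory granule, goblet, Paneth, tuft and stem cells, cell cycle, brush border, lipid absorption, iron and calcium absorption, fatty acid oxidation, cholesterol synthesis, antimicrobial response, interferon response, MHC class II, T cells, B cells, macrophages, mast cells, smooth muscle, fibroblasts, enteric neurons and glia, pancreatic acinar cells, pancreatic islet, stomach, adipocytes, red blood cells, distal intestine, circadian clock, immediate early genes and sex-linked genes. Of the entries, 4 symbols had no row of that name and 18 were below the filter. Each list was tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which tests a list by itself either in one direction or in either direction. P-values were adjusted over the 33 lists. Members were also adjusted over the list alone. The genes named by rule were Nkx2-2, every tested member of the hormone and enterochromaffin lists, up to 3 members of every other list with the smallest unadjusted p, and the 8 largest rises and 8 largest falls past an adjusted p of 0.05, of which there were none. Genes named outside this rule are said to have been chosen after their values were seen. The emphasis on fry in either direction over its one-direction form was also chosen after the values were seen.

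Control and mutant mice carry the same replicate numbers. The deviations of same-numbered libraries from their group means correlated at 0.11, 0.21 and 0.39 across genes for numbers 1, 2 and 3, each above 0.1, so the numbers were taken to pair the libraries. This pairing comes from the values, since the labels do not say what a number shares. Control 1 correlated slightly better with mutant 2, at 0.13. By Xist and Y-linked genes, control 3 and mutant 3 are female and the other 4 libraries male, so the block overlaps with sex. Deviations cancel out within a group, so likeness of the female libraries alone would make the male combinations positive on average. The values for numbers 1 and 2 therefore do not show a pairing beyond sex. Blocked values are printed where they change a call.

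The alternatives fixed in advance were the replicate block, leaving out each library, pseudocounts of 1 and 0.01, a filter at a mean FPKM of 1 and no filter, quantile normalization, trimmed mean scaling, limma without trend, library quality weights and a sex covariate. Alternatives were also added after seeing the data, namely voom on the implied reads, the male libraries only and a pancreatic covariate. The authors' table was compared by description only.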

Results

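RNA from the duodenum of 6-week-old mice was profiled in 3 control and 3 mutant animals, 1 library each. The mutants, named TNint, carried a floxed Nkx2.2 allele over the TN allele (Nkx2.2flox/TN) with Villin-Cre, a Cre recombinase active in intestinal epithelium. From what is known of the study, TN stands for a mutated tinman domain of the transcription factor Nkx2.2, a regulator of enteroendocrine cell fate, and Cre leaves the mutant allele as the remaining copy in the epithelium. The controls carried a floxed allele over a wild-type allele without Cre, and control 3 lacked the Rosa26Tomato reporter allele that the other 5 animals had. The comparison asks how loss of normal TN domain function in the intestine changes duodenal transcripts. The groups also differed in Cre, in the number of Nkx2.2 copies left in the epithelium, and in the TN allele carried by other tissues. With these groups such differences cannot be told apart from the TN mutation in the epithelium. Depth, read from the FPKM intervals, ran from 14.21 M implied reads in control 1 to 25.91 M in mutant 2 (M, megareads).

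Nkx2-2, the targeted gene (mm9 chromosome 2, 147003282 to 147012138, minus strand, protein coding), was measured at 1, 1.03 and 1.27 FPKM in controls and at 0.748, 0.744 and 0.666 FPKM in mutants. Its mean was 1.1 ± 0.149 FPKM in controls and 0.719 ± 0.0461 in mutants (SD, n = 3 each), and each mutant lay below each control. Such full separation is common with 3 libraries per group. It held for 13.1% of all tested rows, 497 with mutants above and 1574 below, where 10% would come up by chance. The log2 fold change was −0.54 (SE 0.16), with an adjusted p of 0.79 over all genes in limma. Of its RefSeq transcripts, NM_010919 had 0.935 ± 0.2 FPKM in controls and 0.396 ± 0.16 in mutants, and NM_001077632 had 0.165 ± 0.054 and 0.323 ± 0.2. The TN allele may still be transcribed, and which exons Cre deletes is not given in the sources used here, so the gene's level is a partial check of the labels.

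Enteroendocrine hormone genes moved in both directions in the mutants. Of 11 tested members, 3 fell and 1 rose when adjusted over the list alone, and none passed over all genes. Tac1, the tachykinin precursor that includes substance P, fell from 8.56 ± 0.473 to 4.38 ± 0.373 FPKM, with a log2 fold change of −0.95 (SE 0.1) and adjusted p = 0.00035 over the list alone. Pyy, peptide YY, fell from 11.2 ± 3.11 to 3.67 ± 1.74 FPKM (log2 −1.65, SE 0.33, adjusted p = 0.0078), and Nts, neurotensin, fell from 2.15 ± 0.65 to 0.703 ± 0.425 FPKM (log2 −1.57, SE 0.39, adjusted p = 0.015). Cck, cholecystokinin, rose from 63.3 ± 11.5 to 115 ± 22.9 FPKM (log2 0.85, SE 0.18, adjusted p = 0.0078). Ghrl, ghrelin, had 64.4 ± 7.75 FPKM in controls and 109 ± 40.5 in mutants, higher in 3 of 3 mutants, with adjusted p = 0.059 over the list alone and 0.021 with the replicate block.

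The remaining hormone genes did not pass over the list alone. Sct, secretin, had a log2 fold change of 0.35 with adjusted p = 0.13, and 0.032 with the replicate block. The log2 fold changes were 0.23 for Gip, 0.23 for Gcg, 0.13 for Sst, 0.8 for Iapp and 1.05 for Gast, which was below 1 FPKM in each library. With 1 library left out these ran from 0 to 0.54 for Gip, 0.02 to 0.39 for Gcg, −0.04 to 0.23 for Sst, 0.29 to 1.06 for Iapp and 0.33 to 1.54 for Gast, and Sct and Gip passed without mutant 1 (adjusted p = 0.016 each) and Ghrl without mutant 3 (0.013). Taken in either direction, the hormone list as a set differed between the groups, with fry adjusted p = 0.0025 over the 33 lists and 0.011 with the replicate block. In 1 direction it was not called against other genes (median log2 0.23, adjusted p = 0.28). The call on Nts was lost without control 2 (adjusted p = 0.062) or without mutant 2 (0.057), and the set was not called in the male libraries only (0.094).

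Enterochromaffin genes were lower in the mutants. Of 8 tested members, 3 fell adjusted over the list alone, and 7 had a negative log2 fold change. Trpa1, a cation channel for irritants that enterochromaffin cells use, fell from 2.33 ± 0.35 to 0.996 ± 0.206 FPKM (log2 −1.16, SE 0.19, adjusted p = 0.004 over the list alone). Lmx1a, a LIM homeobox transcription factor, fell from 0.658 ± 0.0535 to 0.318 ± 0.0788 FPKM (log2 −0.87, SE 0.21, adjusted p = 0.018). Tph1, the rate-limiting enzyme of serotonin synthesis in the gut, fell from 12.7 ± 0.962 to 7.88 ± 2.38 FPKM (log2 −0.71, SE 0.2, adjusted p = 0.023). Each was lower in 3 of 3 mutants.

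Log2 fold changes of the other enterochromaffin members were −0.59 for Ucn3, −0.46 for Fev, −0.23 for Slc18a1, −0.11 for Slc18a2 and 0.11 for Ddc, and none of them passed over the list alone. The list was lower against other genes (median log2 −0.53, adjusted p = 8.7e-04), with adjusted p = 0.58 with an estimated correlation. In either direction its adjusted p was 0.038, and 0.16 with the replicate block. Without control 2, mutant 1 or mutant 3, 1 member passed over the list alone instead of 3. Lmx1a and Tph1 also lost the call with the pancreatic covariate (adjusted p = 0.056 and 0.07) and in male libraries only (0.095 each), and Tph1 without control 1 (0.053).

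Genes of the endocrine secretory granule were lower too. Of 18 tested members, 17 had a negative log2 fold change and 2 fell adjusted over the list alone. Chga, chromogranin A, fell from 36.1 ± 3.93 to 15.5 ± 2.62 FPKM (log2 −1.23, SE 0.14, adjusted p = 9.7e-04 over the list alone), and Chgb, chromogranin B, fell from 90.9 ± 5.05 to 55.7 ± 14 FPKM (log2 −0.73, SE 0.17, adjusted p = 0.032). Scgn, a calcium-binding protein of endocrine cells, was the 1 member with a positive value, at 2.94 ± 0.54 and 4.26 ± 0.27 FPKM (log2 0.53, adjusted p = 0.053). Scgn passed over the list alone without mutant 2 (adjusted p = 0.047) and at a pseudocount of 1 (0.047). It also passed with quantile normalization (0.034), trimmed mean scaling (0.047) and library quality weights (0.046), and in no other alternative. The list was lower against other genes (median log2 −0.3, adjusted p = 2.9e-05), with adjusted p = 0.58 with an estimated correlation. In either direction its adjusted p was 0.042, and 0.092 with the replicate block. Without mutant 2, 10 members passed over the list alone. Without each of the controls in turn or without mutant 3, 1 did, and Chgb also lost its call without mutant 1 (adjusted p = 0.051).

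Enteroendocrine transcription factors had no member past adjustment over the list alone among 16 tested. Neurod1 had 2.22 ± 0.104 FPKM in controls and 1.54 ± 0.293 in mutants (log2 −0.52, adjusted p = 0.13 over the list alone), and Foxa1 had 4.07 ± 0.363 and 3.36 ± 0.185 FPKM (log2 −0.27, adjusted p = 0.22). The list was called in either direction (adjusted p = 0.018), with 0.14 under the replicate block, and not in 1 direction against other genes (adjusted p = 0.37). These 4 lists of enteroendocrine genes were the 4 of the 33 that were called in either direction. The count fell to 1, the hormone list, with the replicate block, with the sex covariate, without control 3 or without mutant 1.

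**Figure D1:**
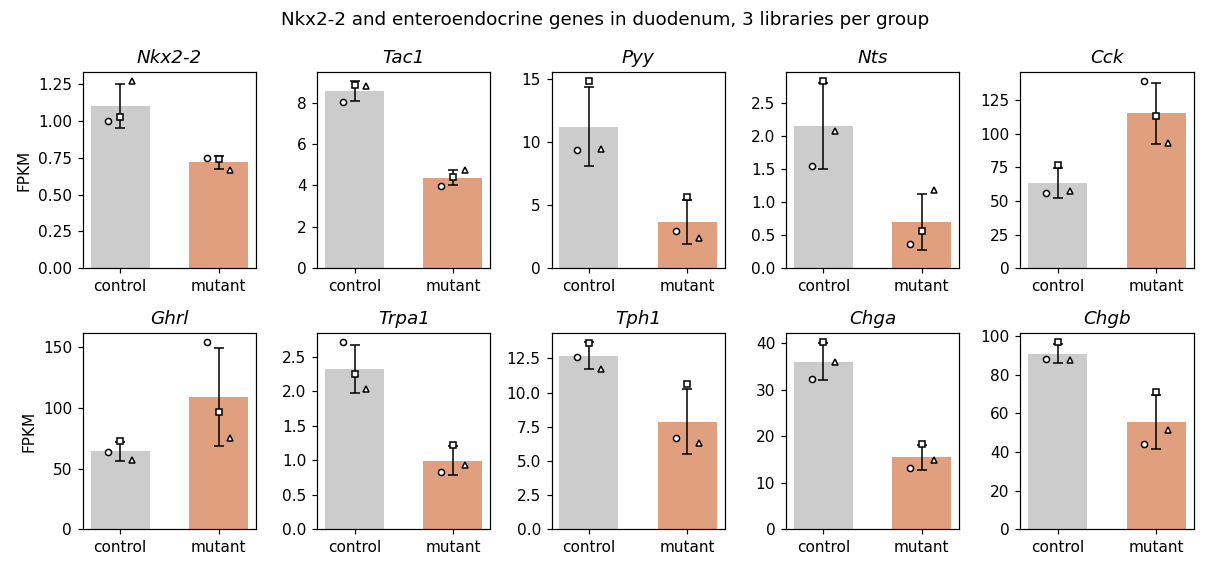
FPKM (vertical axis of each panel, from 0) of Nkx2-2 and 9 enteroendocrine genes in control and mutant duodenum; bars are group means, error bars the SD, and circles, squares and triangles the libraries of replicate 1, 2 and 3. Tac1, Pyy, Nts, Trpa1, Tph1, Chga and Chgb lie lower in each mutant library than in each control library, and Cck and Ghrl higher.

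Smooth muscle genes were lower in the mutants. All 10 tested members had a negative log2 fold change, with a median of −0.44, and 4 fell adjusted over the list alone. Myh11, smooth muscle myosin heavy chain, fell from 76.7 ± 8.23 to 53.2 ± 4.37 FPKM (log2 −0.52, SE 0.1, adjusted p = 0.011), Synpo2 fell from 9.72 ± 1.09 to 6.93 ± 0.129 FPKM (log2 −0.48, adjusted p = 0.011), and Acta2, smooth muscle actin, fell from 198 ± 21.5 to 149 ± 12.5 FPKM (log2 −0.41, adjusted p = 0.024). Lmod1, named because the count is small, fell by 0.41 on the log2 scale (adjusted p = 0.034). The list was lower against other genes (adjusted p = 4.9e-08), with adjusted p = 0.58 with an estimated correlation. With the replicate block 9 members passed over the list alone. Leaving out 1 library at a time gave from 2 members to 10, with 8 without control 1, 10 without mutant 3 and 2 without any of the other 4 libraries.

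Other cells of the wall gave smaller differences. In the fibroblast and matrix list (10 tested, median log2 −0.14, adjusted p = 0.23) Postn, periostin, fell from 10.6 ± 0.344 to 8.56 ± 0.125 FPKM (log2 −0.3, adjusted p = 0.043 over the list alone, 0.087 with the replicate block), and that call was also lost when any 1 library was left out. Lum and Fn1 had log2 fold changes of −0.38 and −0.27. In the enteric neuron and glia list (11 tested, median log2 −0.16, adjusted p = 0.23) none passed, with −0.44 for Tubb3 and −0.16 for Uchl1. The adipocyte list had a median of −0.17 over 4 tested members (adjusted p = 0.85), with −1.28 for Cfd, adipsin (adjusted p = 0.086 over the list alone and 0.0036 with the replicate block), 0.25 for Cidec and −0.36 for Adipoq.

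Pancreatic acinar transcripts varied widely from library to library in both groups. Ctrb1, chymotrypsinogen B1, had 4.61, 87.3 and 2170 FPKM in control 1, 2 and 3 and 727, 648 and 3030 FPKM in mutant 1, 2 and 3. Ctrb1 had a log2 fold change of 3.55, Cela3b 3.41 and Ctrl 3.29, and the list as a set was higher in mutants (13 tested, median log2 3.29, adjusted p = 5.4e-07), with adjusted p = 0.8 with an estimated correlation. None of its members passed over the list alone. The median ran from 1.1 to 5.57 with 1 library left out, and the ratios of group means of its members from 1.3 to 1.94. The islet list had 4 tested members (median log2 0.64, adjusted p = 0.28), with 0.8 for Iapp, which the hormone list also holds, 1.05 for Ins2 and −0.54 for Ins1. The stomach list had 7 (median 0, mean −0.15, adjusted p = 0.62), with 1.03 for Tff1, −0.75 for Pgc and −1.26 for Muc6.

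T cell and interferon genes were higher as sets against other genes, without a member past adjustment over the list alone. The T cell and intraepithelial lymphocyte list had 10 of 12 members with a positive log2 fold change (median 0.28, adjusted p = 2.9e-05, and adjusted p = 0.67 with an estimated correlation). Log2 fold changes were 0.36 for Cd7, 0.28 for Cd8a and 0.91 for Cd8b1. The interferon list also had 10 of 12 (median 0.24, adjusted p = 4.6e-05, and adjusted p = 0.73 with an estimated correlation), with 0.58 for Ifit3, 0.42 for Oas1a and 0.54 for Ccl5. Its median ran from 0.09 to 0.41 with 1 library left out, and Ifit3, Oas1a and Ccl5 passed over the list alone without mutant 2 (adjusted p = 0.038, 0.038 and 0.014), as did Ifit3 with quantile normalization (0.035), trimmed mean scaling (0.032) and the pancreatic covariate (0.043). In male libraries only neither set was called (adjusted p = 0.069 and 0.17).

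The B cell and plasma cell list had a median log2 fold change of −0.35 over 8 members (adjusted p = 0.45), and it was called lower with the replicate block (adjusted p = 0.036) and without mutant 3 (0.023). The log2 fold changes of Cd79b and Cd79a were −0.24 and −0.34. The macrophage and dendritic cell list (11 tested, median log2 0.02, adjusted p = 0.45), the MHC class II list (7, 0.01, 0.51) and the mast cell list (7, 0.31, 0.6) were not called. Their leading members were C1qa at 0.17, Cd68 at −0.11 and C1qc at 0.13, then Ciita at −0.31, H2-Aa at 0.3 and H2-Ab1 at 0.26, then Kit at −0.23, Fcer1a at −0.47 and Mcpt2 at 0.61. Without control 1 the mast cell list turned to a median of −0.42 and was called lower (adjusted p = 0.011).

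Other epithelial lineages had no member past adjustment over the list alone. The goblet list had a median log2 fold change of 0.09 over 11 members (adjusted p = 0.6), with −0.19 for Galnt12, −0.15 for Fcgbp and 0.17 for Spink4. The Paneth list had 0.01 over 10 (adjusted p = 0.6), with −0.4 for Lyz1, 1.91 for Pla2g2a and 0.29 for Nupr1. The tuft list had a median of −0.03 and a mean of 0.07 over 13 (adjusted p = 0.37), with 0.4 for Ltc4s, 0.75 for Gng13 and 0.24 for Il17rb, and was called higher without mutant 3 (median 0.35, adjusted p = 2.1e-05). The stem cell list had −0.14 over 14 (adjusted p = 0.28), with −0.19 for Cd44, −0.41 for Lgr5 and −0.12 for Smoc2, and was called lower without mutant 3 (adjusted p = 0.043). The cell cycle list had a median of 0 over 15 (adjusted p = 0.62), with −0.31 for Bub1, −0.29 for Mki67 and −0.19 for Top2a.

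Absorptive genes showed small differences. In the brush border list (15 tested, median log2 0.04, adjusted p = 0.089) Mep1a, the alpha subunit of the metalloprotease meprin, rose from 5.38 ± 1.71 to 11.6 ± 2.28 FPKM (log2 1.13, SE 0.26, adjusted p = 0.047 over the list alone), a call lost without control 2, mutant 1, mutant 2 or mutant 3 (adjusted p from 0.087 to 0.17), in male libraries only (0.14), with no filter (0.081) and in limma without trend (0.095). Treh and Slc2a2 had 0.28 and 0.2. The lipid absorption list was higher as a set (19 tested, median log2 0.09, adjusted p = 0.0047, and adjusted p = 0.8 with an estimated correlation), a call lost without control 1 (0.24), without mutant 2 (0.19) and under quantile normalization (0.73). Its leading members were Apoc2 at 0.34, Plin2 at 0.15 and Dgat2 at 0.34. The iron and calcium list (9, median 0.06, adjusted p = 0.67) was led by Tfrc at −0.16, Atp2b1 at −0.16 and Fth1 at 0.18. The fatty acid oxidation list (11, 0.02, 0.51) was led by Acaa1b at 0.27, Acot1 at −0.3 and Cpt1a at −0.16, and the cholesterol list (14, 0.07, 0.28) had 0.14 for Dhcr7.

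The last 6 lists were not called either. The antimicrobial list had a median log2 fold change of −0.2 over 10 members (adjusted p = 0.6), with −0.99 for Duox2, −0.38 for Nos2 and −0.21 for Pigr. The distal intestine list had −0.03 over 5 (adjusted p = 0.62), with 0.32 for Slc10a2, −0.91 for Fabp6 and 0.55 for Cubn. The red blood cell list had 0.2 over 5 (adjusted p = 0.51), and its globin genes share near-identical copies, so the values of Hbb-b1 (2.69), Hbb-b2 (−2.05) and Hba-a2 (1.72) are uncertain. The circadian list had −0.12 over 12 (adjusted p = 0.51), with −0.24 for Clock, −0.22 for Nr1d2 and −0.47 for Gm129. The immediate early and heat shock list had a median of 0.03 and a mean of −0.01 over 10 (adjusted p = 0.42), with 0.37 for Fosb, 0.12 for Fos and 0.29 for Atf3. The sex-linked list had −0.12 over 5 (adjusted p = 0.62), with 0.3 for Eif2s3y, −0.12 for Uty and −0.15 for Xist.

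**Figure D2:**
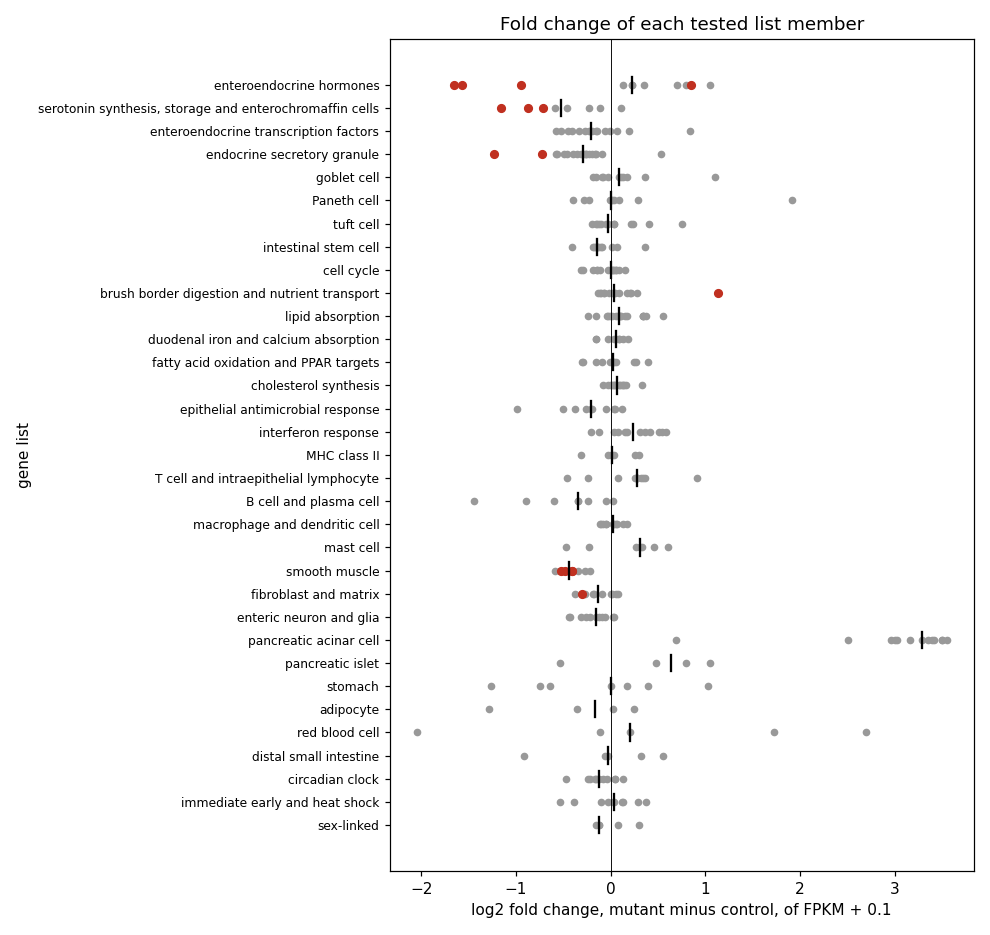
Log2 fold change, mutant minus control, of FPKM + 0.1 (horizontal axis) for each tested member of the 33 gene lists (vertical axis); points are genes, red where adjusted p over the list alone is below 0.05, and black bars are list medians. The 15 red points lie in the hormone, enterochromaffin, granule, brush border, smooth muscle and fibroblast lists, and the smooth muscle members lie together around a median of −0.44 while the hormone members spread from −1.65 to 1.05.

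Across all genes, none of 15864 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.25. At an unadjusted p under 0.05 there were 922 genes, 237 higher and 685 lower, where 793 would come up with no effect. That split was 516 higher and 395 lower with trimmed mean scaling and 360 and 431 with quantile normalization, and the median log2 fold change of all genes was −0.05, 0 and −0.01 in the 3 fits. With the replicate block 2 genes passed, Chga and Mt1, each with an adjusted p of 0.031. Mt1, metallothionein 1, chosen here after its values were seen, had 319, 301 and 376 FPKM in controls and 907, 863 and 1160 in mutants (log2 1.55, SE 0.15), and its neighbour Mt2 had 115 ± 34.1 and 99.4 ± 74.4 FPKM.

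The authors' deposited table calls 7 of its 23284 genes at an adjusted p under 0.05. In that table Mt1 (3.18-fold), Rps16 (2.26-fold) and Mep1a (2.27-fold) were higher in mutants, and Chga (0.444-fold), Trpa1 (0.452-fold), Xlr3b (0.172-fold) and Ces2d-ps (0.0237-fold) were lower. The authors' deposited table gives Tac1 an adjusted p of 0.061. Rps16, Xlr3b and Ces2d-ps are named because that table calls them. In FPKM, Xlr3b had 1.97 ± 0.316 in controls and 0.648 ± 0.176 in mutants, Rps16 had 81 ± 4.9 and 99.7 ± 14.3, and Ces2d-ps had 87.2 ± 41.3 and 87.4 ± 33.2, so that the drop of Ces2d-ps in the authors' deposited table has no counterpart in FPKM. Across 10288 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of limma correlated at r = 0.782, and 85.3% had the same sign. These were single-transcript genes, and those with a low authors' mean were left out.

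The libraries did not fall into groups by genotype. Correlations of log2 values between libraries ran from 0.951 to 0.975 within groups and from 0.947 to 0.985 between them. The first principal component held 40.4% of the variance, and control 3 and mutant 3, the female libraries, lay at its low end, at −28.1 and −32.4, with control 1 at 38.3. Control 2 lay at 18.5, mutant 2 at 5.3 and mutant 1 at −1.8. This order is the reverse of that of the acinar gene Ctrb1 across all 6 libraries. At the low end sex, replicate number and acinar content coincide, and which of them the component follows was not tested. The second held 21.7%. The 20 most abundant genes took from 18.6% of the FPKM total in control 1 to 23.8% in control 3.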

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

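The tests of the first and second patterns were chosen after the results were seen, the shared-read test came from the ratios of the 7 genes the authors called and was written before its genome-wide share was computed, and the splits were written before they were run, though counting lists in either direction and enteroendocrine members was chosen after the real values were seen.

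In the transcript tables, outside the gene comparison, 9 of 19827 RefSeq transcripts passed an adjusted p of 0.05 in limma, 4 higher in mutants (Gjc1, Cd36, 1810019J16Rik and Haus7) and 5 lower (among them Smarcc2, Ptp4a3, Cct3 and Ly6e). Each is listed near 0 in all 3 libraries of 1 group, and the log2 fold changes of the 9 genes lie between −0.15 and 0.1. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 9 transcripts and the highest other split 11, with 4 splits giving at least 9. An interaction of genotype with sex passed for 2 genes, both short RNAs, Snora31 (112 bases) and Mir719 (110 bases), with an adjusted p of 0.014 each in limma. With 1 female library per group its spread comes from the males alone, so it shows no difference between the sexes beyond single libraries.

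The first pattern weighed is that enteroendocrine genes moved apart, with 8 genes lower and Cck higher. A loss of all enteroendocrine cells alike would lower the hormone genes together, but 8 of the 11 were higher and 3 lower, with a mean log2 fold change of 0.01. Each minus their mean in its library, they still differed in either direction (fry in limma, adjusted p = 0.0016 over the 33 lists). With a mean so near 0, this step nearly repeats the call without it (fry, 0.0025) and adds little. The islet list also passed it (fry, adjusted p = 0.024), though not without it (0.92). Pancreatic tissue as the whole cause would take most of the fold changes away, but with a pancreatic covariate 9 of the 9 genes had at least 87.7% of theirs, though the calls on Lmx1a (−0.87, SE 0.21, to −0.8, SE 0.26), Tph1 (−0.71, SE 0.2, to −0.64, SE 0.24) and Chgb (−0.73, SE 0.17, to −0.72, SE 0.21) ended, mostly as standard errors grew, and the enteroendocrine lists called in either direction went from 4 to 1. Less muscle wall would lower a gene expressed in muscle wall by no more than about the smooth muscle genes. A smaller share of muscle wall would not lower a gene expressed only in the epithelium. Of the 8 lower genes, 5 (Tac1, Pyy, Nts, Trpa1 and Chga) lay more than 2 standard errors below that bound (−0.53). For the other 3 (Lmx1a, Tph1 and Chgb) the bound cannot decide, because which cells expressed them was not measured. The 8 genes were picked by their calls in these same values, which favours large falls. With the sex covariate the hormone list was still called in either direction (adjusted p = 0.024), though not in male libraries only (0.094), and other unlabelled differences between the mice were not tested.

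The second pattern is the lower smooth muscle list. Scaling of the FPKM values would bring it to 0, but its median was −0.39 with trimmed mean scaling (median absolute deviation 0.09). Less muscle wall in the mutant pieces cannot be told apart from lower expression in muscle cells. The median of the enteric neuron and glia list, cells of the same wall, lay 0.29 above that of smooth muscle, so it fell less, but it was below 0 by more than its spread (−0.16, median absolute deviation 0.1). The rule that a partial fall leaves the explanation open was set after this value was seen, and the first rule had rejected it.

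The third pattern is that the authors' counts and FPKM disagree for some genes. Reads shared between similar or overlapping genes, left out of a count but divided by Cufflinks, may account for part of it. Of 46 genes whose fold changes differ by more than 2-fold, 41.3% had an authors' mean under 0.5 times the implied reads, against 3.1% of the other genes compared (10321 in all, Fisher's exact test, two-sided, p = 5.5e-17, across genes). The remaining 27 genes do not have that mark. A minimum of 20 was set on the mean implied reads but none on the authors' mean. Noise in low authors' counts could therefore give the same association, and this was not tested. The genes that prompted the test were not taken out. Ces2d-ps had an authors' mean of 0.024 times its implied reads, Rps16 0.17 and Xlr3b 0.44, and the cause in each was not tested.

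Other splits of the 6 libraries bear on the counts, and 10 splits are too few for a share under 0.05. For genes at an adjusted p under 0.05 the real split gave 0 and the highest other 2, and all 10 splits gave at least 0. For genes at an unadjusted p under 0.05 the real split gave 922 and the highest other 1758, with 4 splits as large, and for members adjusted over the list alone it gave 15 and 37, with 4 as large. For lists against other genes it gave 7 and 15, with 7 splits as large. For lists called in either direction it gave 4 and the highest other 1, and for members of the 4 enteroendocrine lists adjusted over the list alone 9 and 1, with 1 split as large in each case, the real one. The labels do not say that the numbers pair the libraries. If they do, the real split compares best with the 3 others that part all same-numbered pairs, and 4 splits are also too few for a share under 0.05. Among those 3 the highest counts were 657 genes at an unadjusted p under 0.05, 6 lists against other genes, 1 member over the list alone, 0 lists in either direction, 0 enteroendocrine members, 2 genes at an adjusted p under 0.05 and 11 transcripts. The splits that keep a same-numbered pair on one side gave the counts of 1758, 15 and 37. This comparison was added after the counts were seen.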

How the results depend on the processing

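Voom on implied reads, the male libraries and the pancreatic covariate were chosen after seeing the data. The alternatives that need counts (DESeq2 size factors, no filter on low counts) were not run, because the files used hold no counts. Nkx2-2 stayed lower and not called in each alternative that tested it, and Tac1, Pyy, Cck, Chga, Trpa1 and Myh11 kept direction and call over the list alone in all 19 alternatives. Where calls changed, the cause was not tested, beyond fewer libraries in those left out.

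Genes past an adjusted p of 0.05 numbered 0, and 2 with the replicate block, 1 with the sex covariate (Mt1, 0.019) and 0 to 3 when 1 library was left out (Snora44 and Snora52 without control 2, Mir215, Pm20d1 and Ndufs5 without mutant 1, Mir7-1 and LOC547349 without mutant 2, each named because the counts are small). Lists called against other genes numbered 7, from 8 to 11 with 1 library left out, and 0 with an estimated correlation and 0 by fry in 1 direction. Lists called in either direction numbered 4, from 1 to 8 with 1 library left out, 1 with the replicate block, 1 with the sex covariate and 0 in male libraries only. The enteroendocrine ones among them numbered 4, from 1 to 4, then 1, 1 and 0, and 1 with the pancreatic covariate. Beyond the blocked values printed in the report, the replicate block changed no other call on Nkx2-2, the lists or the genes named by rule. The transcript calls, the interaction with sex and the tests of the patterns were not run with it.

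With an estimated correlation and by fry, adjusted p was 0.58 and 0.26 for each of the enterochromaffin, granule and smooth muscle lists, 0.8 and 1 for lipid absorption, 0.73 and 0.89 for interferon, 0.67 and 0.72 for T cells and 0.8 and 0.89 for acinar cells. In male libraries only, medians were 0.34 for tuft (called), 0.08 for interferon and 0.13 for T cells (lost) and −0.26 for B cells (called). With the pancreatic covariate they were 0.11 for lipid absorption (lost) and 0.05 for acinar cells (lost, as the covariate is their own level), and 0.52 for cholesterol, −1 for B cells and −0.32 for the circadian list (called). With the replicate block and the sex covariate B cells had −0.35 (called). Quantile normalization gave 0.01 for lipid absorption (lost) and −0.13 for fibroblasts (called).

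With 1 library left out, medians of lists whose call changed ran from 0.19 to 0.42 for hormones (called without mutant 1), −0.1 to 0.16 for Paneth (control 3), −0.34 to 0.35 for tuft (mutant 3), −0.17 to −0.06 for stem cells (mutant 3), 0.02 to 0.07 for brush border (control 3), 0.06 to 0.19 for lipid absorption, −0.1 to 0.09 for fatty acid oxidation (mutant 1), −0.33 to 0.43 for cholesterol (control 1, mutant 3), −0.2 to 0.14 for MHC class II (mutant 2), −0.76 to −0.1 for B cells (mutant 3), −0.42 to 0.71 for mast cells, reversed without control 1 (−0.42), −0.2 to 0 for fibroblasts (mutant 2), −0.24 to −0.13 for neurons and glia (control 2), −0.1 to 1.02 for islet (control 3) and −0.05 to 0.09 for immediate early genes (mutant 2).

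Members adjusted over the list alone ran, with 1 library left out, from 1 to 3 for enterochromaffin, 1 to 10 for granule and 2 to 10 for smooth muscle. They were 1 for enterochromaffin and 1 for granule in male libraries only and with the pancreatic covariate, and for granule 4 at a pseudocount of 1 and 1 with no filter. Transcription factors had 1 with no filter and 1 in limma without trend. Smooth muscle had 9 with the replicate block, 9 with the sex covariate, 10 with quantile normalization, 2 with trimmed mean scaling, 8 with voom, 8 with the pancreatic covariate and 1 in males. Uncalled genes reversed were Gcg (−0.15) and Gip (−0.02) in males, Sst (−0.04) without mutant 2, with a range from −0.04 to 0.23 over the libraries left out, and Ddc (−0.13 without control 3, −0.09 without mutant 2, with a range from −0.13 to 0.28). Over all single genes and alternatives, a call over the list alone was gained in 26 cases and lost in 46.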

Other observations

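Several genes varied from mouse to mouse without regard to genotype, and all genes here were chosen after their values were seen. Pla2g2a, a secreted phospholipase of Paneth cells, had 1390, 16.4 and 28.7 FPKM in control 1, 2 and 3 and 1540, 15.2 and 1490 FPKM in mutant 1, 2 and 3. Reg3g, an antimicrobial lectin, had 4870, 719 and 14200 FPKM in controls and 6440, 734 and 9580 in mutants, and Retnlb, a goblet cell protein, had 35.1, 8.09 and 491 and 798, 5.11 and 334. The cholesterol synthesis gene Sqle was highest in mutant 1 and next in control 1, at 45.3, 30.4 and 17.1 FPKM in controls and 62.8, 25.9 and 17.9 in mutants. The tuft gene Rgs13 had 14.7 FPKM in mutant 1 and 3.17 in mutant 3, and 7.55, 6.43 and 6.9 in controls. Reg3g and Sqle had the same order of replicate numbers in both groups, and the labels do not say what a number shares. Retnlb and Rgs13 did not keep their order, and Pla2g2a was far apart in control 3 and mutant 3.

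Of 3 MHC class I genes on chromosome 17, none passed a test. H2-Q4 had 66.5 ± 2.02 FPKM in controls and 46.6 ± 6.26 in mutants, H2-T23 had 115, 108 and 79.6 FPKM and 179, 134 and 256, and Gm8909 had 36.4 ± 21.4 and 73.3 ± 11.2 (SD, n = 3 each). Each has an adjusted p of 0.79 over all genes in limma, and each is uncertain because these genes share similar copies. Ano1, a channel of the interstitial cells of Cajal, had 3.16 ± 0.229 and 2.05 ± 0.238 FPKM, and Afp, alpha-fetoprotein, had 17.5 ± 5.15 and 5.72 ± 3.33.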
